A study of Amolops torrentis with 15 samples.

How the data were processed

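Whole brains of female torrent frogs (Amolops torrentis) were profiled by RNA sequencing in 15 libraries, in 5 groups of 3 that the labels name by the stimulus: dark contrast, blank contrast, visual, acoustic and audiovisual. Per the labels' protocols, tissue was kept in RNAlater at low temperature, RNA was extracted with Trizol, libraries were made with the NEBNext Ultra RNA kit, and paired reads of 150 bases were sequenced on an Illumina X-ten. The labels do not say what the frogs of the dark and blank contrast groups received, which of them serves as the control for which stimulus, or whether a sample is a single frog or a pool of frogs. All p-values therefore measure only the spread between these samples, which may be partly technical.

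The deposited values are estimated counts of reads per clustered transcript, made by the authors and not normalized, per the file headers; 57.4% of them are whole to within 1e-06. The table also holds FPKM (fragments scaled for feature length and library total) computed by the authors, and the deposited length of each feature in bases. The aligner, assembler, quantifier and their versions are not given in the sources used here, and features are named by cluster numbers with no genome position. Of the 44351 features, 97.8% carry the same cluster number, and 41.8% carry a gene symbol in the deposited Swiss-Prot description (10546 symbols, 4416 of them on several features). Reads of such a gene can be divided between its features, so each value given for a feature is uncertain as a measure of its gene. The lowest deposited FPKM is 0.31 in any library. A feature with an FPKM of 0 in even 1 library is thus not analysed here, which leaves out genes that are silent in some brains. Features near 0 counts are present, with a lowest estimated count of 0.51.

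Estimated counts were rounded to whole numbers. Totals ran from 12071194 counts (dark contrast 1) to 16829356 (audiovisual 3), with a median count of 61 per feature and library. The design fixed before the data were examined planned limma on log2(FPKM + 1) for FPKM, and edgeR's quasi-likelihood test if the table held counts; edgeR was used because it does. Features with a mean FPKM of at least 1 over the 15 libraries were kept (42619, of which 17950 carry a symbol), scaled by TMM and fitted with all 5 groups sharing 1 estimate of the spread (10 residual degrees of freedom, common biological coefficient of variation 0.329). The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The comparisons were the 10 pairs of groups, the 3 stimulus groups against the 2 contrast groups, the audiovisual group against the sum of its parts, and an F test over all groups. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Levels are counts scaled for library total (CPM) after TMM scaling, given as mean ± SD of the 3 libraries of a group. The standard error (SE) beside a log2 fold change is approximate. It is the absolute fold change divided by the square root of its quasi-likelihood F statistic.

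The 23 gene lists, fixed before the data were examined, cover neural genes and markers of other cell types or tissues that a whole brain sample could carry. They were tested in the 12 comparisons (276 list tests) with limma's camera on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists within a comparison. Members were also tested by edgeR with adjustment over the list alone. Genes were named by a rule fixed beforehand: the features past the threshold with the largest changes, up to 10 list members past it when adjusted over the list alone, the immediate early genes fos, egr1, npas4, arc and junb in every comparison, and, as values only where nothing passed, the feature with the smallest p. Where a symbol stands on several features (fos, egr1 and npas4), the most abundant is given unless stated. Features that passed only with a library left out or in another setting fall outside this rule and were chosen after their values were seen. Symbols are those of the Swiss-Prot match, and some named features have another closest match in the deposited NR description and are uncertain: a less abundant fos feature (fosB), both egr1 features (a zinc finger and SCAN domain protein), and those of ITGAM, Luc7l and PLA2G3.

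Library similarity was tested on log2(FPKM + 1), as the design fixed it, by 100000 permutations of the group labels. Response similarity was described by correlating edgeR fold changes across features, beside 20 simulated data sets with no effect; differences of mean log2 CPM were correlated first, and edgeR fold changes took their place after those values had been seen. Alternatives fixed beforehand were a pseudocount of 0.1 (limma), no filter on mean FPKM, an FPKM of at least 1 in at least 3 libraries, median-of-ratios scaling, the sample number as a block, only the 2 groups compared in the fit, and leaving out each library. Those added after the data were seen were limma on log2(FPKM + 1), DESeq2, counts summed per gene symbol, robust empirical Bayes, thinning to equal depth, log2 CPM for library similarity (a measure computed, and its p seen, before that on the scale the design fixed), differences of mean log2 CPM for response similarity, leave-one-out for the lists and for library similarity, and refits of the members that passed when adjusted over the list alone (each library left out, and 7 other settings).

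The code was tested on simulated data drawn from the real means and library sizes over 42619 features. For acoustic against dark contrast, edgeR recovered 2.99% of features changed 2-fold, 58.2% of those changed 4-fold and 74.2% of those changed 8-fold, with 3 false calls. For stimuli against contrasts the shares were 22.4%, 89.6% and 93.9%, with 7 false calls. Camera recovered a simulated shift of the immediate early list by 0.5 (log2) in acoustic against dark contrast and called 0 of the 22 other lists. The simulation was drawn from means and library sizes, not from the correlation between genes. That 0 therefore does not measure how often camera calls a list by chance in the real libraries. Other groupings of the real libraries gave 9 to 45 list calls in 276 tests (median 28). No library pair agreed within sampling noise: the lowest chi-square per degree of freedom was 15.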

Results

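The study asked how the brains of female torrent frogs respond to sexual cues that are heard, seen, or both. Whole-brain RNA was measured in 15 libraries, 3 each for the dark contrast, blank contrast, visual, acoustic and audiovisual groups. Total counts, in M (mega-counts), averaged 12.8 ± 1.18 M in the dark contrast group, 13.5 ± 0.961 M in the blank contrast group and 13.8 ± 1.62 M in the visual group. They averaged 15.3 ± 0.493 M in the acoustic group and 15.6 ± 1.54 M in the audiovisual group (SD, n = 3 in each). Levels below are CPM as mean ± SD of 3 libraries.

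Across the 5 groups, no feature differed after adjustment. The edgeR F test called 0 of 42619 features, with 2019 at an unadjusted p under 0.05, while limma on log2(FPKM + 1) called 0 and DESeq2 called 206. Without audiovisual 2 edgeR called USP54 (edgeR adjusted p = 0.0224) and Cluster-46846.159448 (0.0106), and without audiovisual 3 Cluster-46846.99997 (0.0243). In the 12 comparisons that follow, between 4.42% (acoustic against blank contrast) and 5.68% (dark against blank contrast) of features had an unadjusted p under 0.05, a threshold that passes a share of 0.05 when nothing differs. List calls in those comparisons are camera's at the preset correlation unless stated. Of 100 groupings of the libraries, the real one included, 93 gave at least the 16 list calls found (median of the others 28). Chance was therefore not excluded for any of the 6 lists called. The similarity of libraries of the same group did not pass its test on the scale fixed beforehand. The mean correlation of log2(FPKM + 1) was 0.915 within groups and 0.914 between groups, and after centring each feature the difference was 0.00996 (one-sided permutation p = 0.0688). On log2 CPM it passed (0.0114, one-sided permutation p = 0.0413), and on the fixed scale p was under 0.05 without dark contrast 1 (0.0184), dark contrast 2 (0.0385), visual 2 (0.045) or acoustic 2 (0.048). The leading principal component held 8.64% of the variance, where 7.14% would be an equal share.

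Between acoustic and dark contrast brains, the calls among the fixed lists were a hair cell transcription factor and the immediate early genes. Chance was excluded for neither. Pou4f3 (Cluster-46846.1334) was lower in acoustic (0.612 ± 0.00757 CPM, or 9 to 10 counts per library) than in dark contrast brains (1.67 ± 0.377 CPM), with a log2 fold change of -1.43 (SE 0.34). It passed when adjusted over the list alone (edgeR adjusted p = 0.00997 among 11 features of inner ear genes; 0.864 over all genes tested), and leaving out any of the 6 libraries gave 0.0138 to 0.0412. Immediate early genes, which neurons switch on within minutes of activity, were higher as a list: 24 of 36 features lay above 0, with a median of 0.10 (camera adjusted p = 0.0209). This call was lost with the other setting (adjusted p = 0.945 with an estimated correlation), with no filter (0.0617), with the filter on 3 libraries (0.06) and with sums per symbol (0.0756). It was also lost, and the median turned while camera's direction stayed up, without dark contrast 2 (median -0.03, camera adjusted p = 0.963) and without acoustic 2 (median -0.0022, camera adjusted p = 0.222). Dark contrast 2 had a mean centred level of these genes of -0.81 on the log2 scale, against -0.11 to 0.25 in the other 14 libraries, and also the lowest share of mitochondrially encoded transcripts (4.21%). That share was lowest in the library numbered 2 within each group. No immediate early gene passed alone: log2 fold changes were 0.48 for fos, 0.77 for egr1 (whose features have another zinc finger protein as NR match), 0.94 for npas4, 0.69 for arc and 0.27 for junb (SE 0.349 to 0.589), with edgeR adjusted p of at least 0.297 over the list alone. Among single features edgeR called 0, with 2179 at an unadjusted p under 0.05, limma called 0 and DESeq2 called 35. With only these groups in the fit, edgeR called Cluster-46846.159936 (log2 fold change -6.35, SE 0.408, adjusted p = 0.0145). The smallest p belonged to Lmln, a leishmanolysin-like peptidase, at 8.96 ± 0.766 CPM in acoustic and 2.72 ± 0.833 CPM in dark contrast brains (log2 fold change 1.71, SE 0.276, edgeR adjusted p = 0.639).

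Transcripts encoded by the mitochondrial genome were higher in visual than in dark contrast brains, as a list call at the preset correlation only. All 8 features lay above 0, with a median log2 fold change of 0.40 (camera adjusted p = 3.65e-06; adjusted p = 0.781 with an estimated correlation). When adjusted over the list alone, mt-cyb (log2 fold change 0.46, SE 0.141) and MT-ND1 (0.46, SE 0.14) passed, each with an edgeR adjusted p of 0.0227, against 0.895 and 0.907 over all genes tested. Both lost that call without dark contrast 2 (0.123), visual 1 (0.067) or visual 3 (0.135), and mt-cyb also without dark contrast 1 (0.0528). These transcripts took 6.10 ± 0.796% of the scaled counts in visual, 4.94 ± 0.639% in dark contrast and 5.45 ± 0.688% in blank contrast brains. Cytosolic ribosomal protein genes lay lower, with 68 of 93 features below 0 and a median of -0.08 (camera adjusted p = 0.0136; adjusted p = 0.833 with an estimated correlation). That call ended without dark contrast 1 (median 0.05, camera adjusted p = 0.158), visual 1 (0.453) or visual 3 (0.267), and with limma's values (median -0.04, 0.155 with a pseudocount of 0.1 and 0.175 with 1). For fos, egr1, npas4, arc and junb the log2 fold changes were 0.63, 0.79, 0.57, 0.62 and 0.27, and none passed (edgeR adjusted p of at least 0.492 over the list alone). Lmln had the smallest p here as well (11.5 ± 1.72 CPM in visual brains, log2 fold change 2.07, SE 0.278, edgeR adjusted p = 0.14). No feature was called by edgeR (0, with 2260 at an unadjusted p under 0.05) or limma (0), and DESeq2 called 36. Without dark contrast 1, edgeR called Luc7l (log2 fold change 3.55, SE 0.412, adjusted p = 0.0459).

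In audiovisual against dark contrast brains, ribosomal protein genes were lower and mitochondrially encoded transcripts and immediate early genes higher, as list calls at the preset correlation only. Of 93 ribosomal features 81 lay below 0, with a median of -0.15 (camera adjusted p = 1.72e-07), and 8 of 8 mitochondrial features lay above 0, with a median of 0.31 (camera adjusted p = 9.56e-05). The immediate early median was 0.19 (camera adjusted p = 0.0444). Each of the 3 calls was lost in the other setting (adjusted p = 0.626 with an estimated correlation for each). Without dark contrast 1 the ribosomal median was -0.01 (camera adjusted p = 0.707). Without dark contrast 2, which had the lowest level of these genes, the immediate early median was -0.03 (camera adjusted p = 0.992), and that call was also lost without audiovisual 1 (0.081) or audiovisual 3 (0.091), with limma's values (0.0779 and 0.0911 with pseudocounts of 0.1 and 1) and with sums per symbol (0.0709). Adjusted over the list alone, otof, which encodes the hair cell protein otoferlin, was higher in audiovisual (105 ± 12.9 CPM) than in dark contrast brains (71.5 ± 6.38 CPM; log2 fold change 0.56, SE 0.125, edgeR adjusted p = 0.00609, against 0.786 over all genes tested), and leaving out any library gave 0.00481 to 0.0439. The heat shock factor gene Hsf2 was also higher (28.8 ± 1.49 against 19.0 ± 0.904 CPM; log2 fold change 0.60, SE 0.135, edgeR adjusted p = 0.0249 over the list alone and 0.789 over all genes tested). Its call was lost without any of the 6 libraries (0.0505 to 0.132), with log2 fold changes of 0.559 to 0.637, and held in 5 of 7 other settings (up to 0.0625). For fos, egr1, npas4, arc and junb the log2 fold changes were 0.64, 1.03, 0.92, 0.68 and 0.52, with edgeR adjusted p of at least 0.373 over the list alone. The smallest p was that of Khk, ketohexokinase, the enzyme that starts fructose breakdown, at 10.7 ± 3.15 CPM in audiovisual and 1.45 ± 0.149 CPM in dark contrast brains (log2 fold change 2.88, SE 0.372, edgeR adjusted p = 0.0918; 1.31e-08 with DESeq2 to 0.544 with sums per symbol). By edgeR 0 features passed, with 2228 at an unadjusted p under 0.05, by limma 0 and by DESeq2 30. Without audiovisual 1 edgeR called LHFP (adjusted p = 0.0409), without audiovisual 2 Cluster-46846.159448 (0.00591), and without audiovisual 3 Khk and Cluster-46846.99997 (0.0483 each).

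Acoustic and blank contrast brains differed in no fixed list and in no listed gene. Log2 fold changes were -0.20 for fos, -0.19 for egr1, -0.14 for npas4, -0.31 for arc and -0.25 for junb, each smaller than its SE (0.347 to 0.584). The smallest p belonged to the unnamed feature Cluster-46846.165693, at 81.2 ± 9.70 CPM in acoustic and 35.6 ± 6.77 CPM in blank contrast brains (log2 fold change 1.19, SE 0.17, edgeR adjusted p = 0.27). Among single features edgeR called 0, with 1883 at an unadjusted p under 0.05, limma called 0 and DESeq2 called 33. Without blank contrast 3, CCT7, a chaperonin subunit gene, passed in this comparison (log2 fold change 5.19, SE 0.585, edgeR adjusted p = 0.0322).

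Mitochondrially encoded transcripts were also higher in visual than in blank contrast brains, with 8 of 8 features above 0 and a median of 0.24 (camera adjusted p = 0.00745; adjusted p = 0.835 with an estimated correlation). The call was lost without blank contrast 2 (camera adjusted p = 0.406) or visual 3 (0.404). CKM, the muscle creatine kinase gene, passed when adjusted over the list alone of 12 muscle features (log2 fold change 3.14, SE 0.912, edgeR adjusted p = 0.0478, and 1 over all genes tested). Its level was 10.1, 32.4 and 1.92 CPM in the visual libraries and 1.66 ± 0.521 CPM in blank contrast brains. That call was lost without blank contrast 1 (0.146), 2 (0.115) or 3 (0.112), visual 1 (0.0581) or visual 2 (log2 fold change 1.85, 0.338), and held in 1 of 7 other settings (up to 0.25). For fos, egr1, npas4, arc and junb the log2 fold changes were -0.04, -0.17, -0.51, -0.38 and -0.24 (edgeR adjusted p of at least 0.96 over the list alone). The smallest p was that of the unnamed feature Cluster-46846.112923, at 0.852 ± 0.174 CPM in visual and 0.148 ± 0.00666 CPM in blank contrast brains, or 2 counts per library (log2 fold change 2.45, SE 0.367, edgeR adjusted p = 0.418). Over the alternatives its adjusted p ran from 0.013 (limma, pseudocount of 0.1) to 0.598 (edgeR, a library left out). No feature was called by edgeR (0, with 1987 at an unadjusted p under 0.05) or limma on log2(FPKM + 1) (0), and DESeq2 called 27. Without blank contrast 3, edgeR called CCT7 (log2 fold change 5.15, SE 0.584, adjusted p = 0.0344).

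The list of pituitary markers was higher in audiovisual than in blank contrast brains. Besides the hormone genes pomc and cga, its features carry the symbols PCSK1, PCSK2, CHGA, CHGB, TRHR and SSTR2. PCSK1 (135 to 190 CPM) and CHGB (689 to 959 CPM) were abundant in every library, so the list does not measure pituitary tissue alone. Of 17 features 14 lay above 0, with a median of 0.36 and a mean of 1.12 (camera adjusted p = 6.81e-04; adjusted p = 0.0293 with an estimated correlation), the only list call that held in both settings. Leaving out any of the 6 libraries gave a camera adjusted p of at most 0.00912. The hormone genes pomc (log2 fold change 6.36, SE 1.79) and cga (7.24, SE 2.02) passed when adjusted over the list alone, with an edgeR adjusted p of 0.0274 for each and 1 over all genes tested. The libraries of the group differed widely: pomc was 1815, 54.1 and 7691 CPM and cga 652, 1.28 and 1883 CPM in audiovisual 1, 2 and 3. Outside it, pomc reached 5042 CPM in dark contrast 2 and 1936 CPM in acoustic 2, and cga 101 CPM in acoustic 3. Both calls were lost without blank contrast 1 (0.132), blank contrast 3 (0.0625) or audiovisual 3 (0.122), and without blank contrast 2 (0.077 for pomc, 0.0806 for cga), and held in 4 (pomc) and 3 (cga) of 7 other settings (up to 0.143 and 0.214). Ribosomal protein genes were lower, with 77 of 93 features below 0 and a median of -0.09 (camera adjusted p = 6.81e-04; adjusted p = 0.984 with an estimated correlation; 0.278 without blank contrast 2 at the preset correlation). For fos, egr1, npas4, arc and junb the log2 fold changes were -0.04, 0.07, -0.16, -0.32 and 0.00070 (edgeR adjusted p of at least 0.962 over the list alone). The smallest p was that of lsm14b-a, an RNA-binding protein gene, at 14.4 ± 6.66 CPM in audiovisual and 68.4 ± 18.2 CPM in blank contrast brains (log2 fold change -2.24, SE 0.352, edgeR adjusted p = 0.437). By edgeR 0 features passed, with 1934 at an unadjusted p under 0.05, by limma 0 and by DESeq2 32. Without blank contrast 3 edgeR called CCT7 (adjusted p = 0.0454), and without audiovisual 1 LHFP (0.0115).

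**Figure D1:**
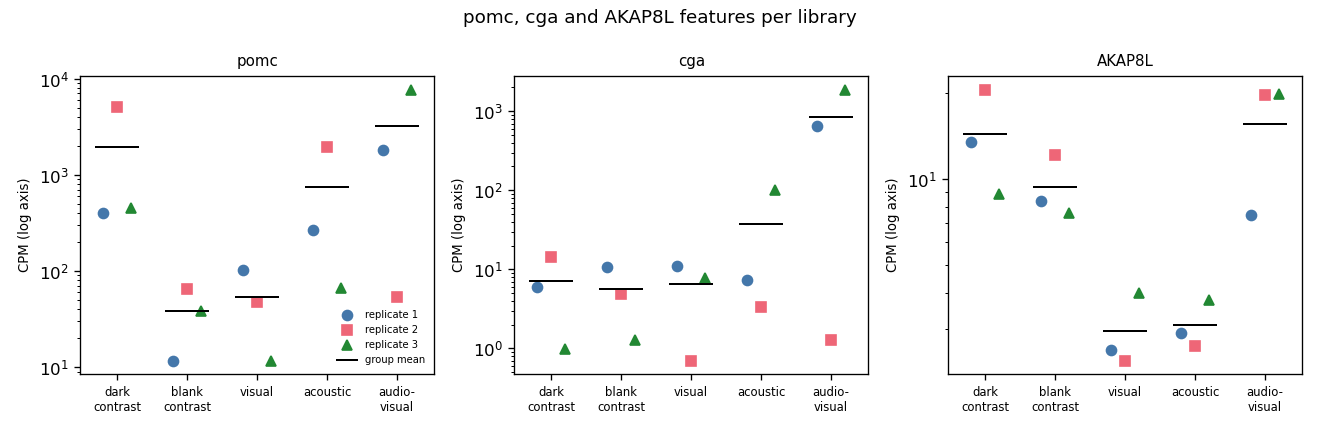
Levels of the pomc, cga and AKAP8L features in each of the 15 libraries, in CPM on a log axis, by group on the horizontal axis, with a bar at each group mean. The highest pomc (7691 CPM) and cga (1883 CPM) values belong to audiovisual 3, while audiovisual 2 has 54.1 and 1.28 CPM; AKAP8L lies below 7.47 CPM in the visual and acoustic libraries and between 7.47 and 20.5 CPM in all others.

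Immediate early genes and genes of inhibitory synapses were lower in dark than in blank contrast brains, as list calls at the preset correlation only. For the immediate early list 26 of 36 features lay below 0, with a median of -0.22 (camera adjusted p = 8.73e-04; adjusted p = 0.524 with an estimated correlation). Without dark contrast 2, whose mean centred level of these genes was -0.81, the median was -0.09 (camera adjusted p = 0.337). Genes of GABA and glycine synapses had 38 of 53 features below 0, with a median of -0.15 (camera adjusted p = 0.00156; adjusted p = 0.345 with an estimated correlation). This call was lost without dark contrast 1 (camera adjusted p = 0.276), though the median was then -0.135. CYR61, a growth factor inducible gene, passed when adjusted over the list alone (6.46 ± 0.989 against 14.6 ± 3.56 CPM; log2 fold change -1.17, SE 0.291, edgeR adjusted p = 0.0448, and 0.777 over all genes tested). It was lost without dark contrast 1 (0.0856) or 2 (0.268), or blank contrast 1 (0.152) or 2 (0.131), and held in 5 of 7 other settings (up to 0.0903). Hsf2 was lower too (19.0 ± 0.904 against 28.3 ± 3.36 CPM; log2 fold change -0.57, SE 0.135, edgeR adjusted p = 0.0356 over the list alone and 0.777 over all genes tested). It was lost without dark contrast 1 (0.0699), 2 (0.074) or 3 (0.0768), or blank contrast 2 (0.0609) or 3 (0.133), and held in 4 of 7 other settings (up to 0.0957). Over the left-out libraries its log2 fold change ran from -0.627 to -0.471. Log2 fold changes of fos, egr1, npas4, arc and junb were -0.67, -0.96, -1.08, -0.999 and -0.52, with edgeR adjusted p of 0.133 for arc, 0.142 for egr1 and npas4, and 0.518 for fos and junb over the list alone. The arc feature was at 66.8, 20.4 and 75.7 CPM in the dark contrast libraries and 109 ± 24.0 CPM in the blank contrast group. The smallest p was that of the unnamed feature Cluster-46846.200327 (3.76 ± 0.341 against 0.759 ± 0.337 CPM; log2 fold change 2.29, SE 0.342, edgeR adjusted p = 0.321). Among single features edgeR called 0, with 2419 at an unadjusted p under 0.05, limma called 0 and DESeq2 called 38.

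**Figure D2:**
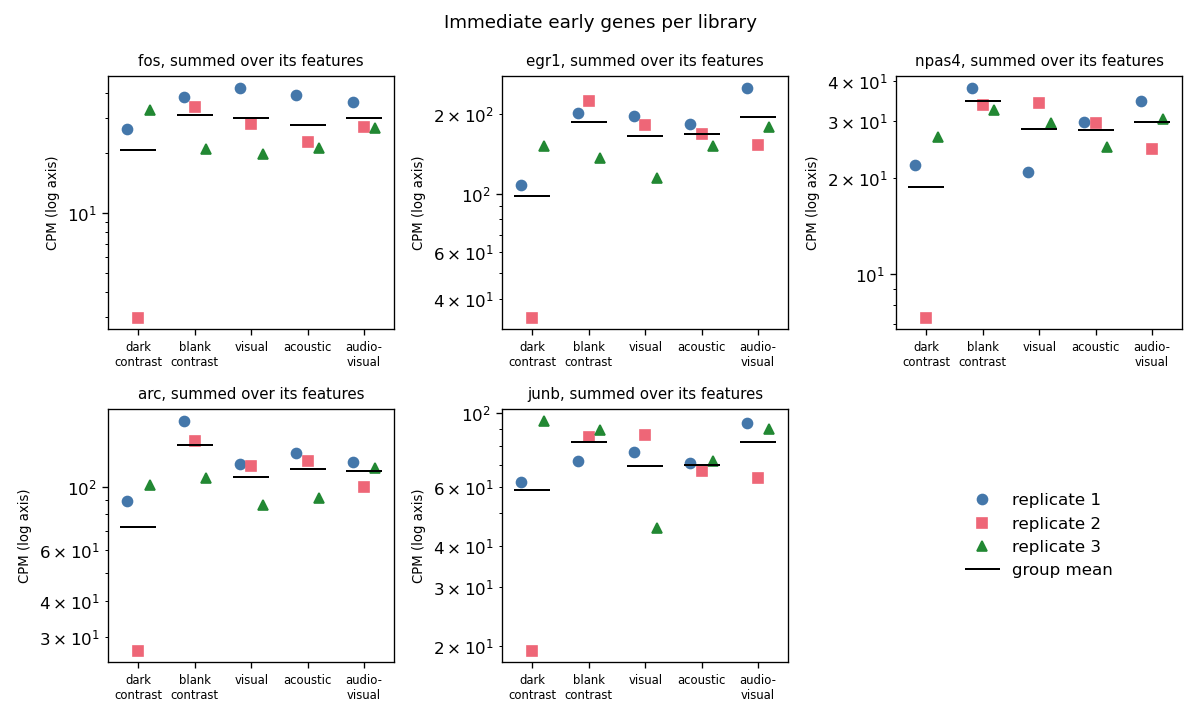
Levels of fos, egr1, npas4, arc and junb in each of the 15 libraries, summed over the features of each symbol and scaled to the total counts of features with a symbol (CPM on that scale, log axis), by group on the horizontal axis, with a bar at each group mean. Dark contrast 2 lies lowest for all 5 genes, at 2.98 CPM for fos, 33.9 for egr1, 7.32 for npas4, 26.8 for arc and 19.3 for junb, while dark contrast 1 and 3 lie within the range of the other groups except for egr1 in dark contrast 1 (108 CPM, below it) and junb in dark contrast 3 (95.2 CPM, above it).

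Acoustic and visual brains, which received different single cues per the labels, differed in no fixed list. Log2 fold changes of fos, egr1, npas4, arc and junb were -0.16, -0.019, 0.38, 0.07 and -0.0042, each smaller than its SE (0.347 to 0.584). The unnamed feature Cluster-46846.155188 had the smallest p, at 110 ± 9.09 CPM in acoustic and 65.7 ± 8.53 CPM in visual brains (log2 fold change 0.74, SE 0.12, edgeR adjusted p = 0.843). No feature was called by edgeR (0, with 2136 at an unadjusted p under 0.05) or limma (0), and DESeq2 called 27. Without visual 2, edgeR called Cluster-46846.159936 (log2 fold change -6.02, SE 0.596, adjusted p = 0.00743).

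When the visual cue accompanied the acoustic one, ribosomal protein genes were lower than with the acoustic cue alone: 82 of 93 features lay below 0, with a median of -0.10 (camera adjusted p = 1.93e-05; adjusted p = 0.915 with an estimated correlation). Inner ear markers were higher, with 8 of 11 features above 0 and a median of 0.38 (camera adjusted p = 0.0386; adjusted p = 0.774 with an estimated correlation). That call was lost without acoustic 1 (0.16) or 2 (0.402) or audiovisual 1 (0.0742) or 3 (0.164). It was also lost with limma's values (0.0632 and 0.0864 with pseudocounts of 0.1 and 1) and with the sample number as a block (0.0508). CYP19A1, which encodes aromatase, the enzyme that makes oestrogens from androgens, was at 9.52 ± 1.65 CPM in audiovisual and 3.99 ± 1.53 CPM in acoustic brains (log2 fold change 1.25, SE 0.375). It passed among 8 features of sex steroid genes when adjusted over the list alone (edgeR adjusted p = 0.0396, and 0.991 over all genes tested), and was lost without acoustic 1 (0.142) or 2 (0.155), or audiovisual 1 (0.0961) or 2 (0.145); it held in 6 of 7 other settings (up to 0.0615). ITGAM, a leukocyte and microglia integrin gene whose feature matches integrin alpha-D in the deposited NR description, had a log2 fold change of 1.48 (SE 0.442, edgeR adjusted p = 0.0429 over the list alone and 0.991 over all genes tested), and was lost without acoustic 2 (0.234) or 3 (0.126) or audiovisual 3 (log2 fold change 0.89, 0.165); it held in 4 of 7 other settings (up to 0.0925). For fos, egr1, npas4, arc and junb the log2 fold changes were 0.16, 0.26, -0.022, -0.0078 and 0.25 (edgeR adjusted p of at least 0.965 over the list alone). The smallest p was that of AKAP8L, which encodes a nuclear protein kinase A anchoring-like protein (log2 fold change 2.33, SE 0.408, edgeR adjusted p = 0.747). By edgeR 0 features passed, with 2090 at an unadjusted p under 0.05, by limma 0 and by DESeq2 35. Without audiovisual 1 edgeR called LHFP (adjusted p = 0.0243), and without audiovisual 2 Cluster-46846.159448 (0.0205).

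Compared with the visual cue alone, the pituitary list was higher in audiovisual brains, with the limit on its members given above. Of 17 features 13 lay above 0, with a median of 0.21 (camera adjusted p = 0.0132, and 0.093 with an estimated correlation). The call was lost without visual 2 (0.0704) or audiovisual 1 (0.114). Within it pomc (log2 fold change 5.89, SE 1.75) and cga (7.01, SE 2) passed when adjusted over the list alone (edgeR adjusted p = 0.0398 for each, and 1 over all genes tested), and both were lost without visual 1 (0.0912), 2 (0.11) or 3 (0.139) or audiovisual 3 (0.157). Each held in 4 of 7 other settings (up to 0.158 for pomc and 0.284 for cga). GLUL, the glutamine synthetase gene of astroglia, was at 30.0 ± 2.06 CPM in audiovisual and 43.7 ± 5.27 CPM in visual brains (log2 fold change -0.54, SE 0.144, edgeR adjusted p = 0.0355 over the list alone and 1 over all genes tested). It was lost without visual 1 (0.175) or 3 (0.159), or audiovisual 1 (0.0564), 2 (0.138) or 3 (0.169), and held in 6 of 7 other settings (up to 0.064). For fos, egr1, npas4, arc and junb the log2 fold changes were 0.0023, 0.24, 0.35, 0.06 and 0.24 (edgeR adjusted p of at least 0.985 over the list alone). Cluster-46846.155188 again had the smallest p (log2 fold change 0.75, SE 0.12, edgeR adjusted p = 0.613). Among single features edgeR called 0, with 1949 at an unadjusted p under 0.05, limma called 0 and DESeq2 called 20. Without audiovisual 1 edgeR called LHFP (log2 fold change -2.09, SE 0.22, adjusted p = 0.015), and with only these groups in the fit PLA2G3 (-1.74, SE 0.125, 0.043).

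With the 9 stimulus libraries set against the 6 contrast libraries, mitochondrially encoded transcripts were higher, with 8 of 8 features above 0 and a median of 0.24 (camera adjusted p = 1.17e-05; adjusted p = 0.768 with an estimated correlation). No left-out library ended that call (camera adjusted p of at most 0.00522). Ribosomal protein genes were lower, with 69 of 93 features below 0 and a median of -0.06 (camera adjusted p = 0.00154; adjusted p = 0.935 with an estimated correlation). The call was lost without dark contrast 1 (median 0.0074, camera adjusted p = 0.893), blank contrast 2 (0.202) or visual 1 (0.0663). Log2 fold changes of fos, egr1, npas4, arc and junb were 0.24, 0.38, 0.27, 0.16 and 0.09 (edgeR adjusted p of at least 0.801 over the list alone). Khk had the smallest p (log2 fold change 1.31, SE 0.234, edgeR adjusted p = 0.74). No feature was called by edgeR (0, with 2002 at an unadjusted p under 0.05) or limma (0), and DESeq2 called 17. Without audiovisual 2, edgeR called Cluster-46846.159448 (log2 fold change -1.46, SE 0.154, adjusted p = 0.0149).

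Whether the audiovisual response differs from the sum of the acoustic and visual responses was tested in either direction. The term was audiovisual minus acoustic minus visual plus the mean of both contrast groups. AKAP8L had the smallest p. Its level was 15.6 ± 7.09 CPM in audiovisual, 3.10 ± 0.614 in acoustic, 2.95 ± 0.914 in visual, 14.3 ± 5.83 in dark contrast and 9.35 ± 2.41 in blank contrast brains. With counts summed per symbol, its audiovisual log2 fold change was 0.114 (SE 0.376) against dark contrast and 0.763 (SE 0.381) against blank contrast. Its departure therefore came mainly from acoustic and visual levels below both contrast groups, not from a rise in audiovisual brains. The departure from additivity was 4.31 (SE 0.555, edgeR adjusted p = 0.0868), and over the other settings the adjusted p ran from 7.55e-10 with DESeq2 to 0.466 with limma on log2(FPKM + 1). It passed without audiovisual 1 (departure 4.65, edgeR adjusted p = 0.00966). GLUL passed when adjusted over the list alone (-0.73, SE 0.189, edgeR adjusted p = 0.0306, and 0.942 over all genes tested). That call held in 6 of 7 other settings (up to 0.0587) and was lost without dark contrast 3 (0.0566), blank contrast 1 (0.0526) or 3 (0.0553), visual 1 (0.103) or 3 (0.0979), acoustic 1 (0.116), or audiovisual 2 (0.0866) or 3 (0.0993). The departures of fos, egr1, npas4, arc and junb were -0.14, -0.05, -0.05, -0.13 and 0.24 (edgeR adjusted p of 0.991 for each over the list alone). By edgeR 0 features passed, with 1923 at an unadjusted p under 0.05, by limma 0 and by DESeq2 46.

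The acoustic and visual responses had correlations across features close to 0, and slightly below it, where they shared no libraries. For acoustic against dark contrast with visual against blank contrast, Pearson's r was -0.0172 and Spearman's rho -0.0273, beside a simulated r of 0.00172 ± 0.00504 (SD of 20 simulations) with no effect. For acoustic against blank contrast with visual against dark contrast, r was -0.0129 and rho -0.0263, beside 0.00135 ± 0.00679. The former was above 0 without blank contrast 2 (0.00379) or visual 1 (0.00372), and the latter was nearest 0 without visual 3 (-0.000382). For acoustic against dark contrast with audiovisual against blank contrast r was -0.0378, beside a simulated -0.000733 ± 0.0052, and with the contrast groups exchanged -0.0336, beside 0.00161 ± 0.00689. For visual against dark contrast with audiovisual against blank contrast r was -0.00336, beside -0.000662 ± 0.00809, and with the contrast groups exchanged -0.00348, beside 0.00205 ± 0.00765. Against shared dark contrast libraries r of the acoustic and visual responses was 0.507, where simulations with no effect gave 0.509, and the covariance was 0.115 where they gave 0.112. Against shared blank contrast libraries r was 0.493 beside a simulated 0.506, and the covariance was 0.109 beside 0.111. For the visual and audiovisual responses against shared dark contrast libraries r was 0.517 beside a simulated 0.509, and the covariance was 0.117 beside 0.112; against shared blank contrast libraries r was 0.505 beside 0.506, and the covariance 0.112 beside 0.111. For the acoustic and audiovisual responses r was 0.494 beside a simulated 0.512 ± 0.00501 for dark contrast, with a covariance of 0.111 beside 0.112 ± 0.00152, and 0.479 beside 0.51 ± 0.00429 for blank contrast, with a covariance of 0.104 beside 0.111 ± 0.00142. Groups of 3 cannot be divided into parts of at least 2 libraries, so part of any excess may come from the shared libraries. The simulations drew each feature independently, so their SD leaves out the correlation between genes and is too narrow to judge chance by. Features are not independent replicates, so these values are descriptions.

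Of the 23 lists, 6 passed the camera test in at least 1 comparison, in 16 of 276 tests at the preset correlation and in 1 with an estimated correlation. The other 17 passed in none, with a smallest adjusted p of 0.0638, for synaptic vesicle genes in visual against dark contrast brains. Next came nuclear genes of oxidative phosphorylation (camera adjusted p = 0.0988), glutamate synapse genes (0.151), dopamine and monoamine genes (0.152), markers of astroglia and ependyma (0.174), thyroid hormone genes (0.221), hypothalamic neuropeptides (0.255) and heat shock genes (0.288), each in the comparison where it came closest. The smallest values were 0.326 for endothelial and choroid plexus markers, 0.336 for red blood cell markers, 0.382 for microglia and leukocyte markers, 0.407 for potassium channels of auditory neurons and 0.412 for myelin genes. Muscle markers (0.431), circadian clock genes (0.487), photoreceptor markers (0.56) and sex steroid genes (0.599) were farthest from the threshold. Adjusted over the list alone, 16 tests of listed features passed, 2 of which (Pou4f3 and otof, above) held with any library of their comparison left out. The 16 came from 13 of 276 combinations of a list and a comparison, each adjusted on its own, where a threshold of 0.05 gives a call in 13.8 when nothing differs.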

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

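The sum over features of each symbol was an alternative chosen after the data were seen. With counts summed per gene symbol, the departure of AKAP8L from additivity passed the threshold (4.32, SE 0.553, edgeR adjusted p = 0.0236; 7.55e-10 to 0.466 over its alternatives). Of the 50 groupings drawn for the fit per feature, 8 gave at least 1 call in this comparison. Groupings were not drawn for the sums per symbol, so chance is not excluded for this call. AKAP8L has 1 feature, so its counts are those used above, where the adjusted p was 0.0868; the unadjusted p was 2.04e-06 among 42619 features and 2.24e-06 among 10546 symbols, so the adjusted p was lower because fewer tests were adjusted for. All 6 acoustic and visual libraries lay below the 9 others, whose range was 7.47 to 20.5 CPM. No explanation was tested for this gene. Outlying samples were not tested for within the groups of 3 libraries.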

How the results depend on the processing

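DESeq2, limma on log2(FPKM + 1), sums per gene symbol, robust empirical Bayes, log2 CPM for library similarity, differences of mean log2 CPM for the response correlations and leave-one-out for lists and library similarity were chosen after the data were seen. The edgeR count of 0 in every comparison was also 0 with no filter, with the filter on 3 libraries, with median-of-ratios scaling, with robust empirical Bayes and with limma on log2(FPKM + 1). DESeq2 called 206 features over all groups; 35, 36 and 30 for acoustic, visual and audiovisual against dark contrast; 33, 27 and 32 against blank contrast; and 38 for dark against blank contrast. It called 27 for acoustic against visual, 35 and 20 for audiovisual against acoustic and against visual, 17 for stimuli against contrasts and 46 for the sum of parts. Limma with a pseudocount of 0.1 called 1 for visual against blank contrast (Cluster-46846.112923). With only the 2 groups compared in the fit, edgeR called 1 for acoustic against dark contrast (Cluster-46846.159936) and 1 for audiovisual against visual (PLA2G3), and of these changes the cause was not tested. Sums per symbol called 1 for the sum of parts (AKAP8L), where fewer tests were adjusted for. Leaving out 1 library gave 0 to 2 calls over all groups and for audiovisual against dark contrast. It gave 0 to 1 for visual against dark contrast (Luc7l, without dark contrast 1), for each stimulus against blank contrast (CCT7 without blank contrast 3; LHFP without audiovisual 1), for acoustic against visual, audiovisual against acoustic and against visual, stimuli against contrasts, and the sum of parts (AKAP8L). The names were chosen after their values were seen. Over all features the sample numbers did not pair the libraries: same-numbered libraries of different groups had a mean correlation of deviations of 0.00687 (-0.035 to 0.0429), none of 30 over 0.1, and 5 of 15 correlated best with their own number. A factor shared by number in fewer genes is not excluded by this. The library numbered 2 had the lowest mitochondrial share in each group (4.21% dark contrast, 4.69% blank contrast, 5.40% visual, 4.66% acoustic, 5.24% audiovisual). With the number as a block, the mitochondrial list in visual against dark contrast had a camera adjusted p of 6.58e-12, against 3.65e-06 without. With the sample number as a block, edgeR called 0 in every comparison and 20 list tests passed, against 16 (15 shared; inner ear markers in audiovisual against acoustic were at 0.0508). Adjusted over the list alone and with that block, GLUL (0.064 against visual, 0.0587 for the sum of parts), CYP19A1 (0.0615), ITGAM (0.0629), Hsf2 in dark against blank contrast (0.0671), cga in audiovisual against blank contrast (0.101) and CKM (0.106) were not past the threshold. The 16 list tests became 13 to 26 with 1 library left out (26 without dark contrast 3), 24 with sums per symbol, and 14 to 18 under the others. Directions turned for ribosomal protein genes without dark contrast 1, in visual against dark contrast (0.0546) and in stimuli against contrasts (0.00735), and for immediate early genes in audiovisual against dark contrast without dark contrast 2 (-0.0258). For immediate early genes in acoustic against dark contrast the median alone turned, without dark contrast 2 (-0.0275) and without acoustic 2 (-0.00215). Among the left-out libraries that ended these calls, the medians ran from -0.0526 to 0.0546, from -0.0498 to 0.00735 and from -0.0258 to 0.139. The 16 list calls stayed past the threshold in 117 of 128 fits in other settings and in 91 of 114 with 1 library left out, all in camera's direction. Of the 128, the 16 with robust empirical Bayes repeat the main camera test and could not be lost. The 3 turned fits were not past the threshold. With an estimated correlation 1 of the 16 calls stayed past it. Named features (fos, egr1, npas4, arc and junb in acoustic against dark contrast not counted), with the lowest and highest value over left-out libraries counted as 1 alternative each, stayed short of the threshold with a value within 1 SE in 359, moved further in 33 and newly passed in 21. The library similarity of 0.00996 passed with log2 CPM (0.0114, one-sided permutation p = 0.0413), and ran from 0.00638 to 0.014 with 1 library left out. Its permutation p was then under 0.05 without dark contrast 1 (0.0184), dark contrast 2 (0.0385), visual 2 (0.045) or acoustic 2 (0.048). The response correlations ran from -0.0287 to 0.00379 and, with the contrast groups exchanged, from -0.0248 to -0.000382; with differences of mean log2 CPM they were -0.0169 and -0.00901. At the depth and spread of these libraries, the simulation of acoustic against dark contrast recovered 2.99% of 2-fold, 58.2% of 4-fold and 74.2% of 8-fold changes; neither depth nor spread was varied in it.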

Other observations

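The tests of a single library, of the group label, of pomc and cga and of the edgeR splits below were chosen only after the results were seen, as were the features named in the next paragraph. Those of depth, of divided reads and of the DESeq2 and list relabelings were written before their own results were seen, though not before the data were examined.

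A few abundant transcripts differed many-fold between libraries of the same group. Cluster-46846.155354, whose closest NR match is a goldfish mitochondrial protein, reached 12762 CPM in blank contrast 2 and 13006 CPM in acoustic 3, against 1766 to 3560 CPM in the other 13 libraries. A feature matching toad lipocalin (Cluster-46846.155782) was at 9794 CPM in dark contrast 1 and 508 CPM in audiovisual 3, with a median of 2342 CPM. The beta globin feature HBB (Cluster-46846.154589) was at 1517 CPM in acoustic 3, with a median of 579 CPM over all libraries. For chromogranin A, a marker of secretory granules, the feature Cluster-46846.160056 ran from 10.4 CPM (visual 1) to 878 CPM (audiovisual 3), while Cluster-46846.154013, whose NR match is another protein, stayed between 103 and 139 CPM. Its swing is much larger than that of the gene. Summed over 4 features and scaled to features with a symbol, the gene ran from 805 CPM (visual 1) to 1797 CPM (audiovisual 3). From visual 1 to visual 2, Cluster-46846.160056 rose from 10.4 to 548 CPM while Cluster-46846.156757 fell from 307 to 74.6 CPM.

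Immediate early genes were lower in dark than in blank contrast brains as a list, and a candidate explanation is a single library. Without dark contrast 2 the median was -0.0921, 42.4% of its size with all libraries. That library was picked because its level was the lowest of the 15, so some loss on removing it was fixed in advance. After thinning every library to the lowest total, the median was -0.204, 93.8% of its size (camera adjusted p = 0.00124). Thinning hardly moves CPM on average, so the median was bound to stay near its size and this test cannot decide on unequal totals. Effects of depth that thinning cannot undo were not tested. Dark contrast 2, with 14.2 M counts, was deeper than blank contrast 1 (12.6 M) and 3 (13.4 M) and below blank contrast 2 (14.5 M). A difference that belongs to the group cannot be told apart from that library here, with so few samples: the exact one-sided p of the group's mean level among all choices of 3 of the 15 libraries was 0.0769, and without dark contrast 2 it was 0.385. That library also had the lowest share of mitochondrially encoded transcripts (4.21%) and the lowest muscle marker level (-0.45 on the centred log2 scale) of the 15, and the second highest pomc (5042 CPM). The mitochondrial share was lowest in the library numbered 2 within every group, so a low share is not particular to dark contrast 2. Whether the frog, its handling or its dissection sets dark contrast 2 apart was not tested.

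The pituitary hormone transcripts pomc and cga differed 659-fold and 2711-fold between libraries, and different amounts of pituitary tissue left on the brain might do this. Of the 21 symbols fixed for the pituitary list 8 were measured. Of these 2 also stand in another list, 1 of them in that of hypothalamic neuropeptides, which the brain itself holds. The table holds only features found in every library, so finding all 8 in every library does not bear on carried tissue (PCSK1 stayed between 135 and 190 CPM and CHGB between 689 and 959 CPM). Tissue of a single fixed composition as the source in all high libraries is argued against, because among the 5 libraries with pomc or cga at 10 or more times the median the ratio of pomc to cga differed 896-fold (212-fold without acoustic 3, which had 66.7 CPM of pomc, and 537-fold without acoustic 2). Dark contrast 2 and acoustic 2, high in pomc only, had ratios of 353 and 588. Audiovisual 1 and 3, high in both transcripts, had ratios of 2.78 and 4.08, so carried tissue of like composition is not argued against for them. The audiovisual stimulus as the whole cause is argued against too, since audiovisual 2 had 1.28 CPM of cga, within the range of the other groups (up to 101 CPM). The ratio bears only on carried tissue as the sole source of both transcripts, not on transcripts made within the brain. Pieces from different parts of the gland, and a response of some frogs only, stay open and were not tested.

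Large differences within groups could come from reads of a gene that were divided differently between its features. Over 4283 pairs of features with the same symbol, deviations from the group means correlated at -0.0111, against 0.00223 for random pairs of like expression. The difference of -0.0133 (SE 0.00835) lay between the bounds set beforehand, so the test left this open. Its pairs came from all symbols with several features, not from those with large differences within groups. A mean over them therefore cannot decide the question for such features. Strongly opposed pairs (r below -0.5) made up 16.2% of same-symbol and 6.16% of random pairs, a count that was not set beforehand.

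The real edgeR count was 0 in every comparison, which any split reaches, so the splits say nothing of chance there. Among the 50 drawn, the highest other count was 5 features over all groups, 1 for stimuli against contrasts and 3 for the sum of parts. At least 1 feature was called in 10, 4 and 8 of them. For the pairwise comparisons the 10 splits are too few for a share under 0.05. The highest other count was 0, 2 and 0 for acoustic, visual and audiovisual against dark contrast, 5, 1 and 0 against blank contrast, and 1 for dark against blank contrast. It was 2 for acoustic against visual, and 3 and 0 for audiovisual against acoustic and against visual. With DESeq2, 2 of 25 groupings, the real one included, reached the real 206 over all groups (highest other 373), and 22 of 25 the real 17 for stimuli against contrasts (highest other 57), so chance was not excluded for either. For the gene lists, 93 of 100 groupings, the real one included, gave at least the real 16 tests past the threshold (highest other 45, median 28), so chance was not excluded for their number. By list, as many tests passed in 86 of the 100 for ribosomal protein genes (real 5), 64 for mitochondrially encoded transcripts (4), 62 for immediate early genes (3), 60 for inhibitory synapse genes (1), 14 for inner ear markers (1) and 11 for pituitary markers (2), so it was not excluded for any of these 6 lists.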
